A study of Mus musculus with 8 samples.

How the data were processed

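RNA-seq libraries were made from mouse yolk sac at embryonic day 15.5, 4 from wild-type (WT) and 4 from Zfp36l3 knockout (KO) conceptuses, which the series describes as biological replicates. The yolk sac is an extraembryonic membrane whose outer visceral endoderm takes up and secretes nutrients and carrier proteins, over a mesoderm layer that holds blood vessels. Zfp36l3 encodes an RNA-binding protein of the tristetraprolin (TTP) family, whose members bind AU-rich sequences in 3′ UTRs and promote decay of the mRNA. The labels give total RNA as the material and a genotype for each library. They give no litter, sex or batch, and they do not say which part of the gene was removed. Replicate numbers were assigned within each group as names only and pair no samples.

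The authors deposited a table of FPKM values (fragments scaled by transcript length and by library size) with 1 row per RefSeq transcript and 1 column per library. Per the submitters' processing notes the reads were mapped with BWA and the genome build was mm10; the versions, the counting program and the use of strand are not given in the sources used here. Without a statement on strand, reads from overlapping antisense genes cannot be separated.

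The table held 27713 transcript rows for 19332 gene symbols, of which 4579 had several rows. In 785 genes with 2 transcripts the division of reads between them varied between libraries as counting noise would (median chi-square per degree of freedom 1.01), so reads had been divided between transcripts and not counted repeatedly, and FPKM values were summed per symbol. The design had assumed 1 row per gene. Symbols were matched to GENCODE M21 (GRCm38, the same assembly as mm10), 18948 by RefSeq accession and 227 by symbol; 157 had no match. A 3′ UTR was annotated for 17608 symbols. Low FPKM values multiplied by transcript length fell on whole multiples of a step per library in 71.1% to 72.9% of cases (tolerance 0.1 read; 20.0% by chance), and the step corresponds to 40519000 to 47893000 reads per library. These depths are estimates, and no count test was run. FPKM values depend on the share of reads taken by a few abundant genes: the globin genes held 1.75% to 12.8% of all FPKM in a library, and Afp 9.15% to 14.1%.

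Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model on genotype, empirical Bayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05) over the 10749 genes with a mean FPKM of at least 1. Log2 differences are KO minus WT on that scale, which understates the change of genes with low values. Single genes and list scores were also tested with a two-sided exact permutation test of the difference in means over the 70 assignments of the libraries, whose smallest possible p is 0.0286. Of 27 gene lists, 26 had at least 4 measured genes and were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data. A list score is the mean over its measured genes of log2(FPKM + 1) minus the WT mean. The 7-mer UAUUUAU, the core TTP-family binding site, was sought in the longest annotated 3′ UTR of each gene, with AUAAAUA as a control sequence. The planned tests of the 7-mer among genes that rose were not run, as no gene rose.

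The lists, tests, naming rule and a first set of alternatives were fixed before the data were examined. The rule named Zfp36l3, then up to 12 genes per direction with an adjusted p under 0.05 and no overlap between groups; with fewer than 5 such genes in all, the 5 genes with the smallest p in each direction are given as values. It added up to 4 members of each list described, the TTP family, and fixed genes of iron handling, visceral endoderm, X inactivation and the Y chromosome. Lists are described by member where they passed camera at the preset correlation or had a member past the threshold adjusted over the list alone; the TTP family and iron lists are also described. This choice of the lists described by member was made after the results, the alternatives included, had been seen. Genes singled out beyond the rule are named as such.

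Alternatives covered pseudocounts of 0.1 and 0.5, no filter and a mean FPKM of at least 5, median-ratio scaling, quantile normalization, removal of globin genes, robust or trend-free empirical Bayes, sample weights, a Y-linked covariate, an adjusted p under 0.1, a fold of at least 1.5, each library left out in turn, camera with an estimated correlation (for the lists and the 7-mer), the 9-mer UUAUUUAUU, 2 copies of the 7-mer and the shortest 3′ UTR. After the data were examined 5 more were added: the highest transcript per gene, removal of a loess trend on transcript length and GC content, a trophoblast covariate, and 2 sets of libraries left out. Results were compared with those of all 35 splits of the 8 libraries into 4 and 4. On simulated data for KO against WT over 10749 genes, with 200 genes changed, the fit recovered 70% of changes of 1.5-fold, 92% at 2-fold, 98% at 4-fold and 100% at 8-fold, 50 genes each, with 8 calls among the 7488 genes left unshifted, as the genes with the 7-mer and the members of a simulated list were shifted too. The simulated noise was independent between genes, unlike in these libraries, and changes were added on the log2(FPKM + 1) scale. The recovery rates therefore set no limit on the changes that the fit could miss here. Further tests of the ribosomal protein difference were run after it was seen. Their values are given in the report without an explanation. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.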

Results

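The data compared the transcriptome of embryonic day 15.5 mouse yolk sac between 4 WT and 4 Zfp36l3 KO libraries, and the question was which mRNAs differ in level when the RNA-binding protein ZFP36L3 is absent. FPKM totals were 206409 to 239276 per library, and the estimated depths were 40519000 to 47893000 reads. Pairwise correlations of log2(FPKM + 1) between libraries were 0.910 to 0.993. The first principal component held 53.1% of the variance and the second 18.5%. WT replicate 1 (-26.1) and KO replicate 1 (39.0) lay at the ends of the first component.

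Zfp36l3 mRNA was almost absent from all 4 KO libraries. The gene lies on chromosome X from 53774048 to 53776394 on the minus strand (mm10, ENSMUSG00000059334) and has an annotated 3′ UTR of 20 nt. Its FPKM was 11.2, 11.8, 13.3 and 14.7 in the WT libraries and 0.028, 0.009, 0.037 and 0.037 in the KO libraries. The KO mean was 0.217% of the WT mean, and the KO values correspond to an estimated 2.66, 0.95, 3.62 and 3.59 reads. Zfp36l3 fell by 3.74 on the log2 scale (SE 0.086, limma adjusted p = 3.75e-08; exact permutation p = 0.0286, the smallest possible). The other TTP family genes were expressed in both groups. Zfp36l2 was 8.92 ± 0.612 FPKM in WT and 10.5 ± 0.751 in KO (SD, n = 4), a log2 difference of 0.22 that passed only when adjusted over the list alone (adjusted p = 0.0309), and that call was lost without WT replicate 2, 3 or 4 or without KO replicate 2 or 4, with a Y-linked covariate and without the 3 trophoblast libraries. Zfp36l1 was 26.8 ± 2.68 and 28.6 ± 2.40 FPKM, and Zfp36, which encodes TTP itself, 15.6 ± 1.34 and 15.9 ± 2.66 (SD, n = 4). The family list did not pass the set test (adjusted p = 0.465). Its mean log2 difference was -0.85 because of Zfp36l3, while its median was 0.06.

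**Figure D1:**
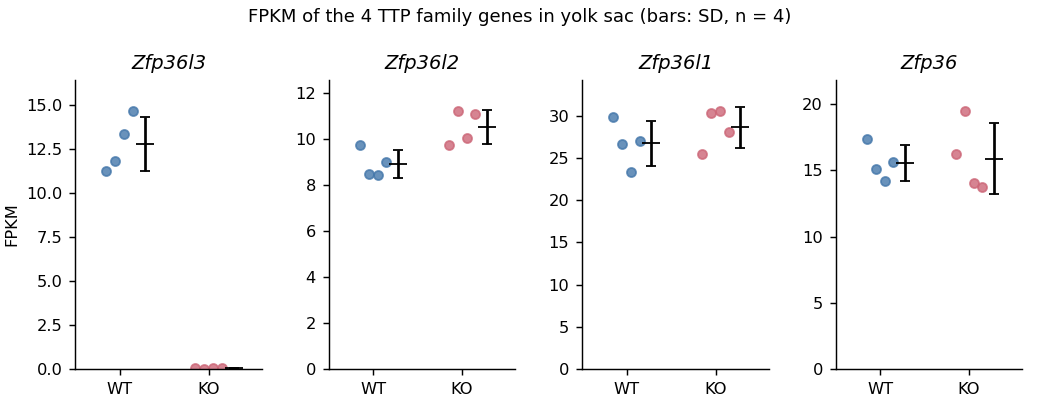
FPKM of the 4 TTP family genes in each library (points), with the mean and SD of each group of 4 (bars). Zfp36l3 was at 11.2 to 14.7 FPKM in WT and at most 0.037 in KO, while the ranges of the other 3 genes overlapped between groups.

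No gene besides Zfp36l3 passed the limma test. Of 10749 genes, 0 were higher and 1 was lower in KO at an adjusted p under 0.05, and the second smallest adjusted p was 0.247. At an unadjusted p under 0.05 there were 664 higher and 958 lower genes, 1622 in all, where 537 would be expected if nothing differed; there were 880 without WT replicate 1, 1070 without WT replicate 3 and 1019 without KO replicate 4. The groups did not overlap in 893 genes, 8.31% of those tested, where chance gives 2.86% on average over the assignments of libraries. How far that share varies between assignments was not computed, so chance is not excluded for it. The smallest p among higher genes belonged to Tm2d1 (10.1 ± 0.683 FPKM in WT, 14.6 ± 0.747 in KO), Cep290, a gene of the ciliary transition zone (2.75 ± 0.409 and 4.50 ± 0.402), Aco2, mitochondrial aconitase (43.8 ± 2.91 and 57.0 ± 0.482), Man1a, a Golgi mannosidase (11.3 ± 0.435 and 14.3 ± 0.331), and Nuak2 (3.46 ± 0.388 and 4.91 ± 0.203; SD, n = 4 throughout). After Zfp36l3, the lower genes with the smallest p were Npm3, a nucleolar protein gene (8.59 ± 0.602 and 5.39 ± 0.664), Samt2 (2.66 ± 0.579 and 1.18 ± 0.311), Znrd1, an RNA polymerase I subunit (7.21 ± 0.730 and 5.23 ± 0.131), and Slc17a2 (1.55 ± 0.396 and 0.635 ± 0.132; SD, n = 4). The KO and WT ranges were separate in all 9 of these genes, and none of them had an adjusted p under 0.247.

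Among reported TTP-family target mRNAs, 3 genes were higher and 1 was lower in KO when p was adjusted over this list alone. Of the 50 genes listed, 31 were measured, and 19 had a positive and 12 a negative log2 difference. At an unadjusted p under 0.05 there were 6 higher and 1 lower of the 31, beside 1622 of all 10749 tested genes. How many calls a chance list of this size would hold was not tested. Serpine1, which encodes the plasminogen activator inhibitor PAI-1, was 3.73 ± 1.26 FPKM in WT and 8.52 ± 2.41 in KO (log2 difference 1.02, SE 0.210). Ldlr, the LDL receptor gene, was 13.1 ± 2.13 and 19.4 ± 1.46 (0.54, SE 0.113), and Plk3, a polo-like kinase gene, 1.5 ± 0.168 and 2.16 ± 0.189 (0.34, SE 0.080). Cebpb, a transcription factor gene, was 3.47 ± 0.665 and 2.14 ± 0.380 (-0.51, SE 0.121; SD, n = 4 throughout). Ldlr and Plk3 have 3 copies of UAUUUAU in the longest annotated 3′ UTR, Serpine1 has 1 and Cebpb has 0. These 4 genes passed adjusted over the list alone (limma adjusted p = 0.0132, 0.0132, 0.0168 and 0.0168), and 0 passed over all genes. The count of higher genes was 1 without WT replicate 3, 2 without KO replicate 2 or KO replicate 3, 5 with sample weights, and 0 without the 3 libraries that held trophoblast mRNAs. The count of lower genes was 0 without WT replicate 3, KO replicate 2, KO replicate 3 or KO replicate 4, with the highest transcript per gene and with the length and GC trend removed. At a mean FPKM of at least 5 it was 0 too, as Cebpb fell under that filter, with 2 higher. The list passed camera at the preset correlation (adjusted p = 0.0167), with adjusted p = 0.671 with an estimated correlation. Over the libraries the list score was 0.037 higher in KO (SD 0.132 in WT and 0.080 in KO), with exact permutation p = 0.657. The member Csf1 was 34.7 FPKM in WT replicate 1 and at most 6.47 in any other library (log2 difference -1.08). The score without Csf1 was not computed. The pass at the preset correlation was lost without WT replicate 2 (adjusted p = 0.105) or KO replicate 2 (0.155). It was also lost without the 3 trophoblast libraries (0.421) and after quantile normalization (0.0548).

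**Figure D2:**
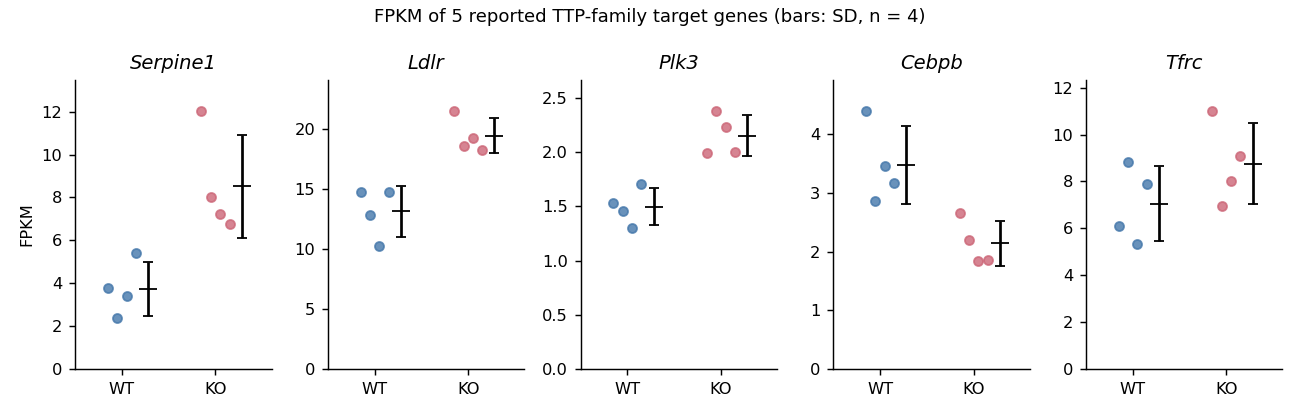
FPKM of 5 reported TTP-family targets in each library (points), with the mean and SD of each group of 4 (bars). Serpine1, Ldlr and Plk3 were higher and Cebpb lower in every KO library than in any WT library, and Tfrc overlapped between the groups.

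Iron genes did not pass the set test as a group, while their score leaned lower in KO (difference -0.08, exact permutation p = 0.0571). The member Lcn2 weighs heavily on that score. It was 37.8 FPKM in WT replicate 1 and at most 1.25 in any other library, with a log2 difference of -1.755. The score without Lcn2 was not computed. The median log2 difference of the list was -0.12. Of 27 measured, 10 had a positive and 17 a negative log2 difference, the list did not pass (adjusted p = 0.779), and 0 members passed adjusted over the list alone, with 1 higher and 1 lower without WT replicate 2 and 1 lower without the 3 trophoblast libraries. The iron score followed the erythroid score over the 8 libraries (Pearson's r = 0.908, exact permutation p = 0.00139, adjusted p = 0.0116). Spearman's rho was 0.976 (exact permutation p = 0.000397, adjusted p = 0.00951), and r was 0.861 without the 2 farthest libraries. Lcn2 was counted in this score, and the relation without that gene was not computed. The relation therefore cannot be read as one shared by the iron genes. The relation within groups was not computed. Tfrc, the transferrin receptor gene, with 2 copies of UAUUUAU, was 7.04 ± 1.601 FPKM in WT and 8.76 ± 1.74 in KO (SD, n = 4; log2 difference 0.28, SE 0.163; exact permutation p = 0.171). Trf, transferrin, was 5466 ± 606 and 6442 ± 497 FPKM, Slc40a1, the iron exporter ferroportin, 45.7 ± 6.16 and 42.7 ± 6.66, Fth1 301 ± 51.3 and 270.4 ± 12.2, and Ftl1, the other ferritin chain, 779 ± 106 and 664 ± 37.4 (SD, n = 4). The Fth1 difference of -0.14 became 0.06 when the trend with length and GC content was removed. Hmox1, heme oxygenase 1 (log2 difference -0.41), Heph, a copper ferroxidase (0.54), Aco1 (0.24) and Slc25a28 (-0.28) had the smallest p of the list, with adjusted p of 0.141 to 0.225 over the list alone.

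Visceral endoderm, lysosome, transporter and stress response lists leaned higher in KO, with few members past a threshold. Afp, the most abundant of the genes named here, was 25228 ± 2411 FPKM in WT and 27771 ± 2461 in KO, Ttr, transthyretin, 958 ± 39.4 and 1196 ± 92.4, and Apoa1 5184 ± 133 and 5225 ± 499 (SD, n = 4). Of 34 genes of secreted proteins and apolipoproteins 24 were higher; Mttp, needed for lipoprotein assembly (log2 difference 0.54), was higher and Apoc1 (-0.43) and Apoe (-0.36) were lower in every KO library than in any WT library, and 0 members passed adjusted over the list alone (adjusted p = 0.0527 for Mttp and 0.0698 for Apoc1 and Apoe). That count of 0 became 2 higher and 2 lower without WT replicate 4, without globin genes, with no intensity trend, with a Y-linked covariate or at an adjusted p under 0.1. It became 3 and 2 with sample weights, 1 higher without WT replicate 1 or 2 or with robust empirical Bayes, and 2 higher with the length and GC trend removed. Of 31 endocytic and apical genes 18 were higher, and 1 passed adjusted over the list alone: Slc39a4, an intestinal-type zinc importer, was 26.5 ± 4.06 FPKM in WT and 45.6 ± 8.64 in KO (SD, n = 4; adjusted p = 0.0187), and that call was lost without WT replicate 1 or 3 or KO replicate 1 or 2, and without WT replicate 1 and KO replicate 1 together. Vil1, villin (0.32), Slc13a4, a sulfate transporter (0.73), and Ezr, ezrin (0.24), followed. Of 37 lysosomal genes 26 were higher, led by Neu1 (0.37), Smpd1 (0.23), Manba (0.29) and Galc (0.20), with 0 past the threshold, and 1 higher without KO replicate 3, without globin genes, at a mean FPKM of at least 5 or at an adjusted p under 0.1. Of 23 transporters 17 were higher, led by Slc39a5 (0.25), Abcc2 (0.43), Slc16a10 (0.42) and Slc34a2 (0.46), and of 26 stress response genes 19 were higher, led by Hyou1 (0.28), Dnajb9 (0.37), Psat1 (0.24) and Sesn2 (0.23), with 0 past the threshold in either list. The 5 lists passed at the preset correlation (adjusted p = 0.0394, 0.00427, 0.00155, 0.00488 and 0.00458 in the order given), with adjusted p = 0.824, 0.671, 0.671, 0.671 and 0.671 with an estimated correlation. In the same order, exact permutation p of the list scores was 0.343, 0.114, 0.0571, 0.229 and 0.0571. KO replicate 1, which held trophoblast mRNAs, had the highest score of the 8 libraries in the endocytic (0.230), lysosome (0.152) and transporter (0.382) lists, and without it the secreted, endocytic, lysosome and transporter lists did not pass (adjusted p = 0.218, 0.0584, 0.0584 and 0.271). The endocytic, lysosome and transporter scores ran against the erythroid score over the 8 libraries (Pearson's r = -0.930, -0.861 and -0.911, exact permutation p = 0.000769, 0.00975 and 0.00221, adjusted p = 0.00961, 0.0487 and 0.0138; Spearman's rho = -0.952, -0.857 and -0.905, exact permutation p = 0.00114, 0.0107 and 0.00456, adjusted p = 0.00951, 0.0536 and 0.0285). Without the 2 farthest libraries r was -0.882, -0.438 and -0.889, so the lysosome relation rests on those libraries. None of these relations was computed within groups. The secreted list was also lost without WT replicate 1 or 4 or KO replicate 2 (0.644, 0.104 and 0.143), and the stress response list without WT replicate 2 (0.0630). With WT replicate 1 and KO replicate 1 left out together, the secreted, endocytic, lysosome and transporter lists lost their call too. Without the 3 trophoblast libraries none of the 5 lists passed (adjusted p = 0.127 to 0.444). The transporter list was also lost with sample weights (0.149), the length and GC trend removed (0.0539) or a trophoblast covariate (0.0973), and the secreted list with median-ratio scaling (0.0854), no filter (0.108), a mean FPKM of at least 5 (0.114), sample weights (0.216), a Y-linked covariate (0.101) or a trophoblast covariate (0.248). Without WT replicate 2 the endocytic list had 4 genes past the threshold over the list alone. It had 2 higher with sample weights or at an adjusted p under 0.1, and 2 higher and 1 lower without the 3 trophoblast libraries.

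Erythroid and ribosomal protein mRNAs were lower in KO on average, and their levels varied together between libraries. Of 19 erythroid genes 18 were lower and 14 passed adjusted over the list alone. The alpha globin genes Hba-a1 (5550 ± 3066 FPKM in WT, 2056 ± 856 in KO) and Hba-a2 (5183 ± 2859 and 1931 ± 798) are near-identical and share reads, and Hbb-b1 was 190.4 ± 107 and 71.7 ± 27.7, and Tspan33 2.80 ± 0.205 and 2.28 ± 0.151 (SD, n = 4). All 40 ribosomal protein genes were lower, and 32 passed adjusted over the list alone, among them Rpl23 (162 ± 24.4 and 117 ± 11.0), Rps18 (211 ± 41.1 and 145 ± 14.7), Rpl37 (39.0 ± 7.60 and 26.5 ± 3.39) and Rpl38 (124 ± 24.9 and 86.6 ± 4.80; SD, n = 4). None of these genes passed over all genes. Both counts were 0 without WT replicate 1, WT replicate 3, KO replicate 1, KO replicate 2 or KO replicate 4, and with the length and GC trend removed. The ribosomal count was also 0 after quantile normalization, and the erythroid count was 0 with robust empirical Bayes and with no filter on low values. With a trophoblast covariate the counts were 0 erythroid and 17 ribosomal, and both were 0 without the 3 trophoblast libraries and without WT replicate 1 and KO replicate 1 together. In the latter case the mean of the erythroid list went from -0.75 to -0.38 and that of the ribosomal list from -0.40 to -0.22. Without globin genes the erythroid mean was -0.40 with 9 genes past the threshold; it was -0.48 with sample weights and -0.50 with no filter. The ribosomal mean was -0.25 after quantile normalization. The lists passed at the preset correlation (adjusted p = 5.24e-06 and 3.66e-16), with adjusted p = 0.671 for each with an estimated correlation. The erythroid score was 0.470, -0.341, 0.368 and -0.497 in WT and -1.38, -0.740, -0.326 and -0.554 in KO, so the groups overlapped (exact permutation p = 0.0857). The ribosomal score differed by -0.40 with overlapping groups (exact permutation p = 0.0571). Over the 8 libraries the 2 scores correlated with Pearson's r = 0.988 (exact permutation p = 0.000223, adjusted p = 0.00558) and Spearman's rho = 0.952 (exact permutation p = 0.00114, adjusted p = 0.00951), among 25 lists compared with the erythroid score. Without KO replicate 1 and WT replicate 1, the 2 farthest libraries, r was 0.967. The ribosomal difference of -0.40 (SE 0.154) was -0.21 (SE 0.0993) with the length and GC trend removed and -0.06 (SE 0.0429) with the erythroid score held fixed. With both scores centred on their group means, r was 0.982 (exact permutation p = 0.00347 over 576 pairings within groups) and rho was 0.976 (exact permutation p = 0.00521). On the centred erythroid score the 2 farthest libraries were KO replicate 1 and WT replicate 4, and r was 0.954 without them. The labels give no batch. Across genes, the moderated statistic rose with transcript length (Spearman's rho 0.433, across genes, which are not independent replicates), and ribosomal protein and globin transcripts are short.

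**Figure D3:**
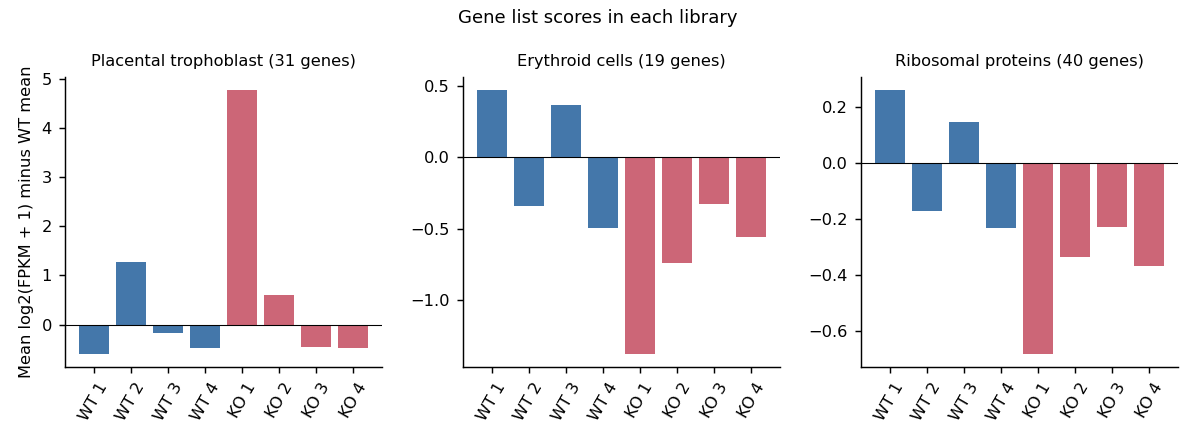
Score of the trophoblast, erythroid and ribosomal protein lists in each library (bars from 0), on the scale of mean log2(FPKM + 1) minus the WT mean. KO replicate 1 stands at 4.76 in the trophoblast panel, and the erythroid and ribosomal panels show WT replicates 1 and 3 above 0 and the other 6 libraries below.

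Placental trophoblast mRNAs were abundant in 1 library. The score of the 31 measured genes was 4.76 in KO replicate 1, 1.26 in WT replicate 2, 0.593 in KO replicate 2 and below 0 in the other 5 libraries. Of the members the naming rule took, Prl2c3 was 77.7 FPKM in KO replicate 1 and at most 3.01 elsewhere, Prl2c2 27.5 and at most 1.52, and Prl2c5 51.9 and at most 2.28; these prolactin-family genes are close paralogs that share reads. Slco2a1 was 29.5 ± 2.51 FPKM in WT and 35.8 ± 4.48 in KO (SD, n = 4). All 31 genes had a positive log2 difference and 0 passed adjusted over the list alone. KO replicate 1 was the highest library for 30 of the 31. The filter on mean FPKM admits genes that are high in 1 library, so the shared sign adds no support. The list passed at the preset correlation (adjusted p = 4.83e-05), with adjusted p = 0.824 with an estimated correlation and 0.989 at the preset correlation without KO replicate 1. Its score gave exact permutation p = 0.571.

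Interferon response and mesothelial genes leaned lower in KO. Of 20 interferon response genes 19 were lower: Ifitm3 was 20.1 ± 4.07 FPKM in WT and 12.1 ± 3.15 in KO, Isg15 7.70 ± 3.71 and 3.76 ± 1.46, Ifit1 2.22 ± 1.26 and 0.975 ± 0.361, and Rtp4 8.06 ± 2.34 and 5.07 ± 1.93 (SD, n = 4). None passed adjusted over the list alone, while 3 passed toward lower without KO replicate 4, and 1 without WT replicate 2 or KO replicate 3, at a mean FPKM of at least 5 or at an adjusted p under 0.1. WT replicate 3 had the highest score (0.361). Of 24 mesothelial and mesenchymal genes 20 were lower, with Tcf21 (log2 difference -0.43), Upk1b (-0.61), Hand2 (-0.34) and Upk3b (-0.65) having the smallest p and 0 past the threshold; KO replicate 1 had the lowest score (-0.917). The lists passed at the preset correlation (adjusted p = 0.000377 and 0.0167), with adjusted p = 0.762 and 0.824 with an estimated correlation. Their scores gave exact permutation p = 0.0857 for interferon and 0.4 for mesothelial genes. The interferon list was lost with sample weights (0.149). The mesothelial list was lost without WT replicate 1, WT replicate 4 or KO replicate 1 (adjusted p = 0.205, 0.0614 and 0.385), with sample weights (0.396), a Y-linked covariate (0.0612) or a trophoblast covariate (0.187), and without the 3 trophoblast libraries (0.160). The mesothelial mean of -0.30 was -0.09 without KO replicate 1 and 0.05 without WT replicate 1 and KO replicate 1 together (adjusted p = 0.558).

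In 2 further lists that did not pass, 1 gene each passed adjusted over the list alone. In the parietal endoderm and basement membrane list (16 measured, 10 lower, adjusted p = 0.494), Fst, which encodes the activin antagonist follistatin and has 4 copies of UAUUUAU, was 3.81 ± 1.10 FPKM in WT and 1.77 ± 0.381 in KO (SD, n = 4; log2 difference -0.78, adjusted p = 0.0113 over the list alone). Pth1r (-0.28), Sparc (-0.34) and Serpinh1 (-0.30) followed. The parietal list passed without WT replicate 3 (adjusted p = 0.0249). It did not pass there with an estimated correlation. In the cholesterol synthesis list (32 measured, 14 higher, mean 0.01, median -0.02, adjusted p = 0.463; 0.00426 without WT replicate 4, with adjusted p = 0.579 with an estimated correlation) Ldlr passed (adjusted p = 0.0273 over the list alone). That call was lost without WT replicate 2 or any 1 of the KO libraries, with a trophoblast covariate and without the 3 trophoblast libraries. Ebp (-0.30), Pmvk (-0.26) and Hmgcr (0.26) followed. The macrophage (18 measured), endothelial (22), decidual (8), hypoxia and glycolysis (27), cell cycle (32), CCR4-NOT and mRNA decay (32), imprinted (31), immediate early (25) and mitochondrial (17) lists did not pass (adjusted p = 0.463, 0.756, 0.465, 0.298, 0.109, 0.496, 0.496, 0.465 and 0.894) and had 0 members past the threshold. In other settings 2 decidual genes passed toward lower without WT replicate 2 and 1 toward higher with no filter, and 1 imprinted gene toward higher without WT replicate 4 or with a Y-linked covariate. The hypoxia list had 1 higher and 1 lower with sample weights and 1 higher with no filter, and the mitochondrial list 1 and 1 with sample weights and 1 higher after quantile normalization. The cell cycle list, with 27 of 32 genes lower, passed toward lower without WT replicate 4, KO replicate 3 or KO replicate 4 (adjusted p = 0.000562, 0.000285 and 0.0351), and toward higher without the 3 trophoblast libraries (0.0247). With an estimated correlation these gave adjusted p = 0.858, 0.814, 0.894 and 0.935. The hypoxia list passed toward higher without WT replicate 4 or KO replicate 1 (0.0345 and 0.00788), and the immediate early list toward lower without KO replicate 2 (0.0219). With an estimated correlation these gave adjusted p = 0.858, 0.784 and 0.767. With the length and GC trend removed the mitochondrial and cell cycle lists passed (0.000527 toward higher and 0.0264 toward lower), with adjusted p = 0.657 and 0.736 with an estimated correlation. Other settings with a pass were the Y-linked covariate for the cell cycle (4.89e-05, lower), hypoxia (0.0272, higher) and cholesterol (0.00268, higher) lists, median-ratio scaling for the cell cycle list (0.0338, lower), sample weights (0.0105), the trophoblast covariate (0.00469) and the absence of WT replicate 1 and KO replicate 1 (0.00687) for the hypoxia list toward higher, and the absence of the 3 trophoblast libraries for the immediate early list (0.000957, lower). With an estimated correlation none of these passed (adjusted p = 0.622 to 0.935). The mitochondrial list had a negative mean (-0.03) and a test direction toward higher, and its mean was 0.12 with the length and GC trend removed, 0.03 with median-ratio scaling, 0.016 with quantile normalization and 0.014 without WT replicate 3.

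The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were detected in 7 libraries and nearly absent from WT replicate 4, where they were 0.014, 0.012, 0.020 and 0.004 FPKM. Xist, the RNA that coats the inactive X chromosome, was 54.9 FPKM there and at most 0.641 in the other 7. Ddx3y was 7.13 to 10.5 FPKM in those 7. By these mRNAs WT replicate 4 was female and the other 7 libraries were male. The WT group was thus mixed in sex, and the KO group was not. The Y-linked list (4 measured) and the list of X inactivation genes and X-linked partners (6 measured) did not pass (adjusted p = 0.0614 and 0.463); the mean of the latter was -0.19 and its median 0.03, with a test direction toward higher. The X list passed without WT replicate 4 (adjusted p = 0.0345) and with a Y-linked covariate (0.0230), and the Y-linked list without WT replicate 1, 2 or 3, with sample weights or with no filter (adjusted p 0.0174 to 0.0331). With an estimated correlation these gave adjusted p = 0.579 and 0.635 for the X list and up to 0.842 for the Y-linked list. None passed.

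Genes with UAUUUAU in the 3′ UTR were higher in KO, on average, than genes without it. Of the 10518 tested genes with an annotated 3′ UTR, 3094 had at least 1 copy and a mean log2 difference of 0.03, and 7424 had none and a mean of -0.06. The difference of 0.0919 passed camera at the preset correlation (p = 6.33e-08) and not with an estimated correlation (p = 0.0624). For the control sequence AUAAAUA, in 2692 genes, the difference was 0.0354 (p = 0.0638 at the preset correlation). With 3′ UTR length, transcript length and GC content held fixed across genes, the difference was 0.0363 for UAUUUAU and -0.0193 for the control; for UAUUUAU it was 0.0238 with no filter on low values. No gene rose at the adjusted threshold.

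**Figure D4:**
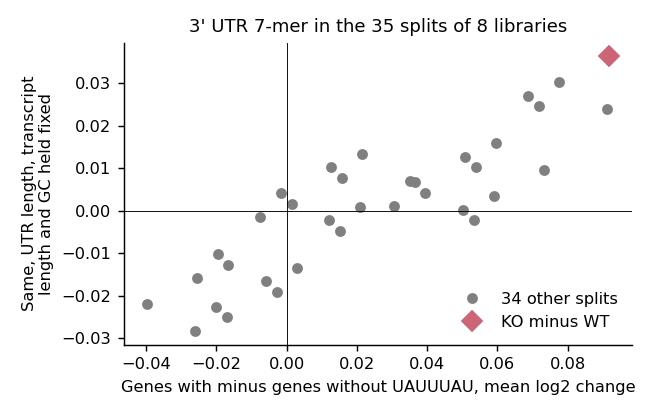
Mean log2 difference of genes with UAUUUAU minus genes without it, as measured (horizontal) and with lengths and GC content held fixed (vertical), for the KO and WT libraries (diamond) and the other splits of the 8 libraries (points). The KO and WT split has the highest value on both axes, 0.0919 and 0.0363, and the highest of the other splits are 0.0913 and 0.0302.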

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

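All tests of explanations in this part were chosen after the results were seen. A library was singled out where its gap to the nearest of the other 3 in its group divided by the group's range exceeded Dixon's critical value; 24 of 212 such comparisons (80 genes and 26 list scores in both groups) met this, where chance, at about 1 in 20, gives 11.

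WT replicate 4 stood apart in Xist (54.947 FPKM), Ddx3y (0.014), Eif2s3y (0.012), Uty (0.004), the Y-linked score (-1.914) and the score of X inactivation genes and partners (0.922). It was also apart in Znrd1 (6.121 FPKM against at least 7.457), the cholesterol score (0.230) and the cell cycle score (-0.365). WT replicate 1 stood apart in Samt2 (3.526 FPKM against at most 2.411), Ttr (899.777 against at least 971.474) and Sparc (787.351 against at most 561.954). WT replicate 3 stood apart in Ifit1 (4.1 FPKM against at most 1.775), Rtp4 (11.552 against at most 7.074) and the interferon score (0.361). KO replicate 2 stood apart in Nuak2 (5.211 FPKM against at most 4.853), Sesn2 (5.734 against at least 7.275) and the parietal endoderm score (-0.161).

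KO replicate 1 stood apart in Upk1b (6.493 FPKM against at least 12.599), Upk3b (6.102 against at least 15.973), Fst (2.336 against at most 1.631), Sparc (367.857 against at least 502.241), Slc16a10 (4.248 against at most 2.344) and the transporter score (0.382). The same library held placental trophoblast mRNAs: 90.3% of the 31 measured genes were over 4 times their median of the 8 libraries, against 45.2% in WT replicate 2 and 9.68% in KO replicate 2, and among abundant members, chosen after their values were seen, Prl3b1 was 476 FPKM, Ctsj 329, Tpbpa 311 and Ctsq 182. Of the 31 genes, 4 had a median of at least 1 FPKM over the 8 libraries and 1 was also in another list. Genes with a lower median passed the filter, a mean FPKM of at least 1, only through libraries where they were high. That filter therefore largely set the 90.3%. The knockout alone as the cause is argued against by 3 KO libraries whose score lay below the highest WT score, and another tissue in place of yolk sac by the Afp share of 13.9% of FPKM in this library, above the lowest of the others (9.15%). Trophoblast tissue carried along at dissection may account for these mRNAs and stays open as a candidate explanation.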

How the results depend on the processing

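Zfp36l3 was the gene called lower, and 0 genes were called higher, under all 26 alternatives, 5 of them chosen after seeing the data; the Zfp36l3 difference ranged from -6.65 to -3.66 (adjusted p 2.65e-09 to 6.66e-05). The count of lists passing, 11, was 0 with an estimated correlation, 5 without the 3 libraries with trophoblast mRNAs, 6 without WT replicate 1 and KO replicate 1 together, and 6 to 13 with each library left out, 6 being without KO replicate 1; the cause was not tested. It was 8 with sample weights and 8 with a trophoblast covariate. The 7-mer difference ranged from 0.0378 (length and GC trend removed) to 0.113, and at 0.0919 it lost its call with an estimated correlation (p = 0.0624). With that correlation it passed at a mean FPKM of at least 5 (p = 0.00619), after quantile normalization (0.0239), without KO replicate 3 (0.0334) or KO replicate 2 (0.0470), with the highest transcript per gene (0.0483) and with the length and GC trend removed (0.00345), and p was 0.0514 to 0.179 in the other alternatives. The erythroid and ribosomal lists passed under all 26 alternatives at the preset correlation, the secreted protein list in 14. No paired analysis was possible because the labels give library names and no replicate numbers shared between groups. In 38 cases a list that passed lost its call without a change of sign. The cause of the changes of sign was not tested. With sample weights, log2 differences became -0.067 for Zfp36, -0.025 for Prl2c3, -0.014 for Prl2c2, -0.012 for Apoa1 and -0.19 for the trophoblast list. With a trophoblast covariate they became -0.00424 for Zfp36 and -0.030 for Apoa1, and with a Y-linked covariate -0.10 for Eif2s3y and -0.065 for Kdm5d. Without the 3 libraries with trophoblast mRNAs they became -0.16 for Zfp36, -0.072 for Prl2c2, -0.052 for Prl2c5, -0.10 for Apoa1 and -0.043 for the trophoblast list. Without WT replicate 1 and KO replicate 1 they became -0.030 for Apoa1, 0.053 for the mesothelial list and -0.31 for the trophoblast list. Fth1 became 0.059 with the length and GC trend removed. With single libraries left out, Zfp36 ranged from -0.0801 to 0.0790, Apoa1 from -0.0305 to 0.0701, Eif2s3y from -0.0198 to 1.17, Kdm5d from -0.0167 to 0.67, the TTP target list from -0.0035 to 0.0877 and the trophoblast list from -0.11 to 1.64. Genes estimated at a few reads, such as Zfp36l3 in KO, are limited by depth.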

Other observations

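The tests of explanations in this part were chosen after the results were seen, except that of Slc39a10, whose prediction was written before its value was known; the splits of the libraries were also examined after the fits.

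Metallothionein and zinc transporter genes were singled out from the 10749 tested genes after their values were seen. Mt1 was 332 ± 105 FPKM in WT and 153 ± 60.2 in KO and Mt2 394 ± 148 and 152 ± 76.0; these proteins bind zinc and their genes are induced by it. Slc30a2, a zinc exporter to vesicles, was 9.57 ± 0.799 and 5.40 ± 1.58, while the importer Slc39a4 was 26.5 ± 4.06 and 45.6 ± 8.64 (SD, n = 4). The Slc30a2 and Slc39a4 ranges were separate between groups (exact permutation p = 0.0286, the smallest possible), and in Mt1 and Mt2 only WT replicate 4 and KO replicate 3 crossed (exact permutation p = 0.0571). None passed over all genes (limma adjusted p = 0.249 to 0.269). The acute-phase gene Saa3 was 124 ± 41.4 and 49.6 ± 19.6 FPKM, and Sftpd, a surfactant protein gene, 6.06 ± 3.87 and 1.39 ± 0.581 (SD, n = 4), without overlap. Saa3 and Sftpd were also singled out after their values were seen, and neither passed over all genes (limma adjusted p = 0.249 for each). Groups were without overlap in 893 tested genes, and Sftpd was 11.5 FPKM in WT replicate 1 against at most 5.53 elsewhere. As a hypothesis, lower zinc in the KO tissue would also raise Slc39a10 and lower Slc30a1. Slc39a10 differed by 0.0487 (SE 0.092) and Slc30a1 by -0.16 (SE 0.152), so the prediction of more than 2 standard errors was met by neither gene, and the hypothesis stays open because neither value excludes it. A differing share of blood cells could also contribute: the Mt1 and Mt2 mean correlated with the erythroid score at Pearson's r = 0.755 (exact permutation p = 0.0274; Spearman's rho 0.762, exact permutation p = 0.0368; r = 0.750 without the 2 farthest libraries), a relation chosen after the fact and not adjusted. Both quantities were lower on average in KO, so the difference between groups enters this correlation. The relation within groups was not computed. Without the 3 libraries with trophoblast mRNAs the difference of the Mt1 and Mt2 mean was -0.96 (SE 0.727) against -1.24 with all libraries. An effect of those 3 libraries cannot be told apart, with 5 libraries left.

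Genes next to Zfp36l3 on chromosome X leaned higher in KO. All 7 measured genes within 200 kb had a positive log2 difference, 3 of them with an unadjusted p under 0.05. The 7 were not tested as a set, and the median log2 difference over all tested genes was -0.03. The 7 neighbours too were examined after the results were seen. Xlr, on the same strand and 724 bp upstream of Zfp36l3 (53777118 to 53797706, mm10), was 7.77 ± 0.849 FPKM in WT and 10.8 ± 1.40 in KO, without overlap. AW822252 was 1.82 ± 0.302 and 2.51 ± 0.335, and Cxx1a 11.3 ± 1.01 and 13.2 ± 0.640 (SD, n = 4). Their limma adjusted p was 0.249 to 0.287. In the other 4, LOC100504039 (0.17), Cxx1b (0.15), 4933416I08Rik (0.12) and Cxx1c (0.09), the groups overlapped and the unadjusted p was 0.105 to 0.498. Hprt, farther away, was 48.2 ± 5.99 and 43.9 ± 2.51. Of the Rhox homeobox cluster, with 3 genes measured and not tested as a list, Rhox5 was 175.2 ± 23.1 and 170.6 ± 15.1 FPKM (SD, n = 4), and Rhox6 and Rhox9 were 19.03 and 29.8 FPKM in KO replicate 1 and at most 6.83 and 3.11 elsewhere. KO replicate 1 was also the library with abundant trophoblast mRNAs, so these values of Rhox6 and Rhox9 cannot be read as a difference between the groups. In WT replicate 1, Lcn2, of the iron list, was 37.8 FPKM against at most 1.25 in the other libraries. Csf1, of the TTP target list, was 34.7 there against at most 6.47.

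The higher mean of genes with UAUUUAU may reflect the loss of a protein that binds it, as a hypothesis. The real split had the largest difference of the 35 splits (1 of 35; 0.0919 against 0.0913 for the highest other), also with lengths and GC content held fixed (1 of 35; 0.0363 against 0.0302), the smallest share that 35 splits can give. This argues against a chance division of the libraries by a narrow margin, and the unadjusted difference did not pass with an estimated correlation (p = 0.0624). A trend with length and GC content as the whole cause is argued against by the difference of 0.0378 left when that trend was removed (p = 0.00345 with an estimated correlation). Without the libraries with trophoblast mRNAs the difference was 0.0303 with lengths and GC content held fixed. That value has no spread, and no splits were run on the libraries left. The difference as measured did not pass there with an estimated correlation (camera p = 0.142). An effect of those libraries cannot be told apart. Genes with 1, 2 and 3 or more copies exceeded genes with none by 0.0365, 0.0375 and 0.0324 with lengths and GC content held fixed in a fit over all genes, which places 3 or more copies below 1 copy. A fit among genes with the 7-mer alone, with its own slopes on lengths and GC content, gave the opposite sign, 0.0151 (SE 0.0105) for 3 or more copies minus 1, so a dependence on copy number was not shown and the hypothesis stays open.

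Other splits of the libraries bear on the counts. The 1 gene called in either direction is the deleted gene itself (1 of 35 splits, highest other 0), and a count of 0 higher genes is met by any split (35 of 35, highest other 0), so nothing about chance follows from either comparison. The 1622 genes at an unadjusted p under 0.05 were matched or exceeded in 2 of 35 splits, the real one included, with 2032 as the highest other, so chance is not excluded. The 11 lists that passed were matched or exceeded in 22 of 35 splits, with 16 as the highest other, so chance is not excluded for that count. The correlation of the moderated statistic with transcript length was as large in 9 of 35 splits and reached 0.539, which points to a structure of the libraries beyond genotype.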
